A study of Homo sapiens with 16 samples.

How the data were processed

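RNA from 16 cultured MSC samples of the human umbilical cord was amplified and biotin-labelled for single-colour Affymetrix Human Transcriptome arrays, per the labels' protocols. The deposited table holds log2 values of 70534 probe sets for each sample, and its scale, background correction, normalization and genome build are not given in the sources used here. That the scale is log2 was read from the values, which lay between 2.23 and 14.3. Transcriptome Analysis Console 1.0.0.234 is named in the submitters' processing notes, without a role. Each column is 1 sample, and no pair of libraries held identical values.

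Probe sets were named with the platform annotation, and 306 symbols were updated through Entrez gene identifiers, of which 21497 matched the reference gene table. Of 67539 transcript clusters, 23781 probes had 1 gene symbol, 1543 had several and 42215 had none listed. Probes with several symbols named no gene. XIST, TSIX and Y-linked genes (359 clusters) were left out. The brightest probe stood for each of 22347 genes, of which 504 had more than 1 probe. Detection calls were not used. A background level was taken as the 95th percentile of the 23 background probe sets of each array, 5.81 to 6.24. Of the genes, 29.6% to 37.0% lay above it. The level follows the highest sets, such as those with 3 and 4 GC bases (5.92 to 6.16). The median of the sets was 3.02 to 3.09, so a gene below the level can still be expressed. Group means of the level were 5.88 to 5.89 at early and 6.10 to 6.16 at late passage. Rises of dim genes with passage may therefore also be overstated. Of the 24 genes named for the passage comparison, 18 had a lower group mean below that level, as had 17 and 15 of 24 for the junction and Wharton's jelly comparisons, and folds of such genes may be understated.

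Means of 6 groups were fitted to all samples in limma 3.58.1 (R 4.3.3) with lmFit and eBayes, which shares 1 estimate of the spread, and 13 contrasts were tested. Genes were called at a Benjamini-Hochberg adjusted p under 0.05, two-sided. Errors of fold changes are moderated standard errors. The median SD within groups was 0.104 in early cord tissue and 0.0518 to 0.0743 in the other groups, so the shared spread is a compromise between them. The samples, tests, gene lists, rule for named genes and alternatives not said below to be added later were chosen before the data were examined. The rule took up to 12 genes per direction for the passage mean and the means of both sources against cord tissue, and up to 5 for the other comparisons, among genes with adjusted p under 0.05 and at least a 2-fold change. For mean comparisons the change had to have the same sign in each source or passage, and for pairwise ones every sample of one group had to lie above the other's. Genes set by common inherited deletions or other inherited variants were not named by the rule, nor were HLA genes other than HLA-DRA and HLA-G. Olfactory receptor, immunoglobulin, T-cell receptor, KIR and amylase genes were left unnamed too. Where fewer than 3 genes passed, the 3 of smallest p were named. Examples of a list were the members with the largest absolute change.

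The 28 gene lists were MSC positive surface markers, MSC negative (haematopoietic) markers, pluripotency genes, cell cycle and mitosis, DNA replication, p53 targets and senescence, senescence-associated secretory factors, interferon response, NF-kB and inflammatory response, and collagens. They also held matrix glycoproteins and proteoglycans, matrix remodelling enzymes, contractile and smooth muscle genes, TGF-beta and BMP response, osteogenic, chondrogenic and adipogenic genes, and HOX and positional genes. Further lists were trophoblast, decidual stromal, epithelial, endothelial and neural markers, hypoxia and glycolysis, cholesterol and lipid synthesis, unfolded protein and stress response, Wnt signalling and immunomodulatory genes. The median log2 difference over all genes was within 0.1 of 0 in each comparison, and with both scalings in the 4 mean comparisons. Of 814 listed genes 736 were measured and 78 were not. Lists were tested with camera at a preset correlation of 0.01, adjusted over 112 tests (28 lists in 4 mean comparisons), which made 37 calls. None of the 37 held with a correlation estimated for each list. The rotation test fry made 46 calls, 29 of them shared with camera. Its PValue tests whether a set's genes move, on balance, one way, its Mixed p-value whether they change in either direction, and neither compares a list with other genes.

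The calculation was tested on simulated data with 200 changed genes among 22347. Each gene had its real mean over all samples and its pooled spread, the same in every group. For the passage comparison 82% of genes with a log2 change of 0.25 and 98% at 0.5 were recovered, and 13 of 203 calls were false. For the junction against cord tissue, averaged over passages, 52% and 94% were recovered. For the same sources at early passage 26% at 0.25, 78% at 0.5 and 94% at 1 were recovered, and at late passage 32%, 66% and 94%. The real spread of early cord tissue was the largest, so recovery at early passage may be overstated. A shift of 0.3 in the interferon list was called by camera for the passage and junction comparisons, and no other list was. Genes were simulated independently, so this does not test camera on lists whose members are correlated. In the real data the estimated correlation of the interferon list was 0.722 for the passage comparison. Alternatives were quantile normalization, subtracted array medians, a filter on dim genes, a trended and robust prior, the replicate number as a block, array weights, the mean of a gene's probes, only the compared groups, every probe, a 2-fold minimum, omission of the late junction samples, and omission of each sample in turn. A poly-A control covariate, omission of small RNA genes and omission of 2 outlying libraries were added after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.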

Results

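The study profiled mesenchymal stromal cells (MSCs), the plastic-adherent fibroblast-like cells of connective tissue, grown in culture from the human umbilical cord. Cells came from 3 sources: cord tissue, the cord-placenta junction, and Wharton's jelly, the gelatinous connective tissue of the cord. Each source was sampled at early passage (below passage 5) and at late passage (above passage 15). The 16 samples formed 6 groups, with 3 samples each except early cord-placenta junction and early Wharton's jelly, which had 2 each. Each sample was 1 whole-transcriptome array, and the median log2 signal over the tested genes lay between 4.96 and 5.01 in every library. A higher value means a higher array signal, and the number of arrays limits the precision. The description of the 3 late cord-placenta junction samples names cord tissue, whereas their title, source and tissue labels name the junction, and the groups follow the latter. These arrays correlated with those of late cord tissue at 0.976 to 0.979, below the lowest value of 0.997 within late cord tissue. Nothing in the labels says that samples of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

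The first comparison asked how late-passage cells (n = 9) differed from early-passage cells (n = 7) on average over the 3 sources. Genes of cell division fell together. MKI67, the proliferation marker, fell by 2.79 on the log2 scale (SE 0.24), as did the mitotic kinesins KIF20A (−2.61, SE 0.20) and KIF11 (−2.54, SE 0.20) and CDC20, an activator of the anaphase-promoting complex (−2.23, SE 0.20). All 35 measured genes of the cell cycle and mitosis list fell, as did 31 of the 32 DNA replication genes, among them the ribonucleotide reductase subunit RRM2 (−2.15, SE 0.16) and thymidine kinase TK1 (−1.72, SE 0.16). The counts adjusted over the list alone were also 35 and 31. Both lists moved down by camera (adjusted p = 8.67e-15 and 5.21e-13), but neither call held at adjusted p = 0.505 and 0.446 with an estimated correlation. Interferon response genes moved the other way. Of 32 measured members 31 rose, also 31 adjusted over the list alone, led by the 2'-5'-oligoadenylate synthetase OAS2 (2.63, SE 0.39), the antiviral enzyme RSAD2 (2.57, SE 0.25) and IFI44L (2.48, SE 0.23). The camera test gave adjusted p = 3.84e-11 for this list, and adjusted p = 0.505 with an estimated correlation.

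Genes of the extracellular matrix changed in both directions with passage. The interstitial collagenase MMP1 had the lowest log2 fold change of the genes named by the rule, −3.12 (SE 0.23, 8.72-fold), and the hyaluronan link protein HAPLN1 fell by 2.41 (SE 0.23). Of 24 collagen genes 15 rose and 2 fell, counts that were the same adjusted over the list alone. COL5A1 rose by 0.75 (SE 0.05) and COL1A1 by 0.60 (SE 0.04), whereas COL6A3 fell by 0.59 (SE 0.11). The collagen list gave adjusted p = 0.000564 by camera and adjusted p = 0.436 with an estimated correlation. Among matrix glycoproteins and proteoglycans 16 of 39 rose and 12 fell, the same counts as adjusted over the list alone. The median of this list, 0.05, turned to −0.05 with quantile normalization, and its mean was −0.02. Fibulin FBLN2 rose by 1.51 (SE 0.14) and the hyaluronan synthase HAS2 fell by 1.57 (SE 0.23). Of the matrix remodelling enzymes 9 of 31 rose, including the aggrecanase ADAMTS5 (2.42, SE 0.42), and 12 fell, as they did adjusted over the list alone. In the contractile and smooth muscle list 16 of 29 fell, including the transcriptional coactivator MYOCD (−1.41, SE 0.14), and 4 rose, or 16 and 5 adjusted over the list alone.

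HOX and positional genes, transcription factors that mark body position, fell in 33 of 54 cases and rose in 5, with PRRX1 at −1.35 (SE 0.13) and HOXB7 at −0.89 (SE 0.06). Their list gave adjusted p = 0.00161 by camera and adjusted p = 0.436 with an estimated correlation. Of the cholesterol and lipid synthesis genes 15 of 25 fell, including the sterol oxidase MSMO1 (−1.05, SE 0.06), and 2 rose. This list gave adjusted p = 0.00254 by camera and adjusted p = 0.674 with an estimated correlation. The complement genes CFB (2.58, SE 0.22) and C3 (2.26, SE 0.28) rose, and 5 of 28 members of the NF-kB and inflammatory response list rose and 4 fell (4 and 3 adjusted over the list alone). Senescence-associated secretory factors rose in 6 of 36 cases and fell in 12, with the prostaglandin synthase PTGS2 at −1.37 (SE 0.23), or 5 and 10 adjusted over the list alone. Targets of p53 and senescence genes rose in 4 of 26 cases and fell in 14, with the lamin LMNB1 at −1.58 (SE 0.13). That list was not divided by the direction its genes take in senescence. Its counts, here and below, therefore show neither more nor less senescence. Of 19 measured MSC surface markers 8 fell (7 adjusted over the list alone), including ALCAM (−0.76, SE 0.06) and PDGFRA (−0.72, SE 0.07), and 1 rose, ENG (0.26, SE 0.04). The HOX, cholesterol and p53 counts were the same adjusted over the list alone. CD44 fell by 0.31 (SE 0.12) on its brightest probe, but the mean of its probes gave 0.26 with adjusted p = 0.0573 by limma.

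The other lists of the passage comparison held members that went both ways. Rises and falls numbered 5 and 16 of 28 for the unfolded protein and stress response, 5 and 17 of 34 for hypoxia and glycolysis, and 7 and 12 of 31 for the TGF-beta and BMP response. They numbered 12 and 9 of 35 for Wnt signalling, 8 and 7 of 27 for immunomodulatory genes, 2 and 7 of 18 for osteogenic genes, 11 and 6 of 22 for chondrogenic genes, and 9 and 7 of 20 for adipogenic genes. In the lists for other cell types they numbered 8 and 2 of 14 for haematopoietic markers, 7 and 5 of 22 for pluripotency genes, 11 and 5 of 32 for trophoblast markers, and 6 and 4 of 17 for decidual stromal markers. They numbered 7 and 10 of 28 for epithelial markers, 7 and 8 of 27 for endothelial markers, and 3 and 13 of 25 for neural and neural crest genes. These counts were the same adjusted over the list alone, except for haematopoietic (9 and 2), adipogenic (9 and 8), trophoblast (11 and 4) and endothelial genes (7 and 7). The camera test left the lists of this paragraph, NF-kB, both senescence lists, matrix glycoproteins, remodelling enzymes, contractile genes and MSC surface markers uncalled, with adjusted p from 0.0658 to 0.968. Median and mean differed in sign for the NF-kB, chondrogenic, adipogenic and Wnt lists. Only 2 of the 14 haematopoietic markers and 2 of the 22 pluripotency genes lay above the 95th percentile of the background probes. The same held for 2 of the 18 osteogenic, 3 of the 22 chondrogenic, 4 of the 20 adipogenic and 3 of the 32 trophoblast genes. With quantile normalization the median turned sign for the haematopoietic, pluripotency, matrix glycoprotein, chondrogenic, epithelial, Wnt and immunomodulatory lists, and for Wnt signalling also with array medians subtracted.

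**Figure D1:**
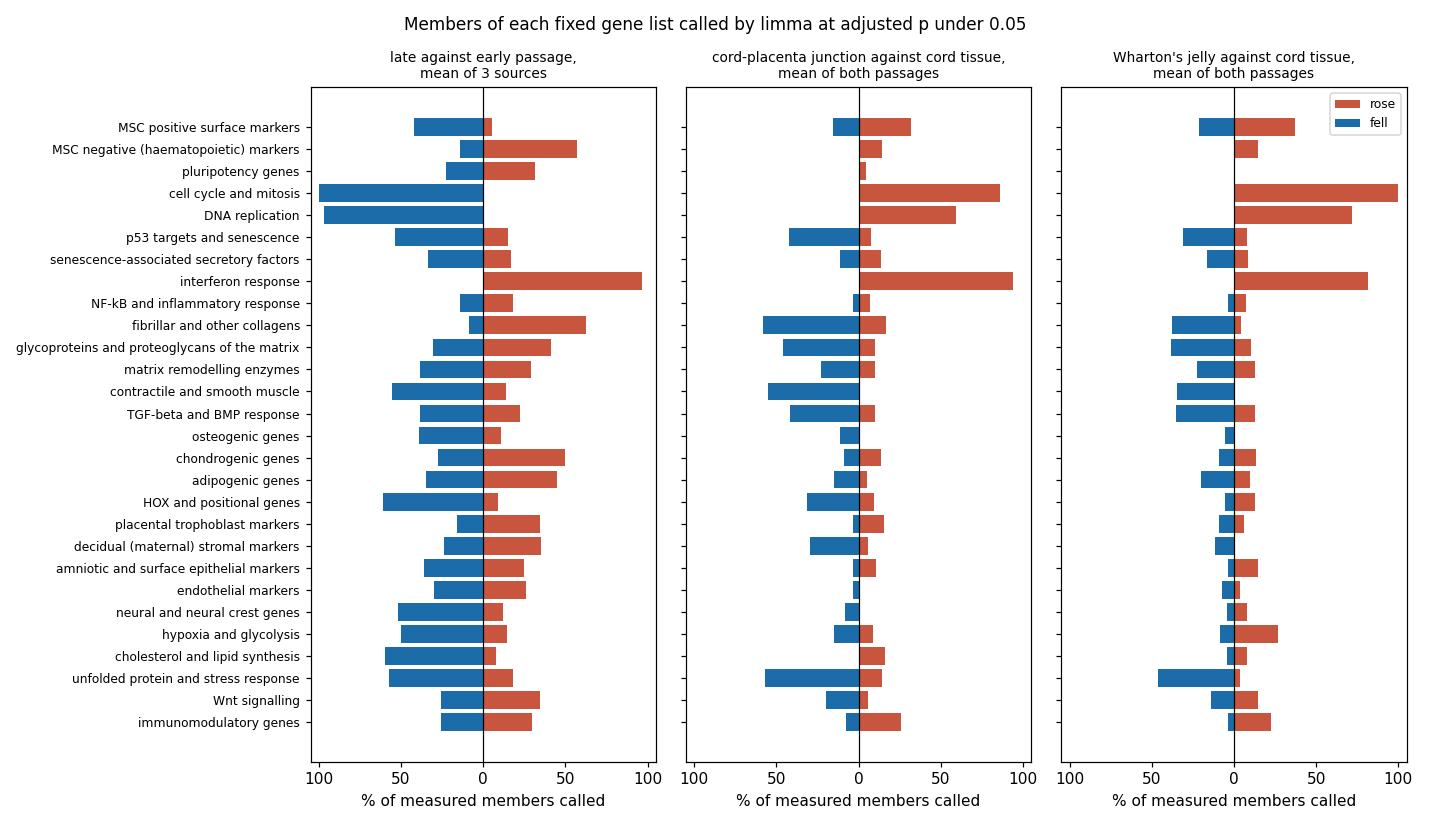
Share of each list's measured members called by limma at adjusted p under 0.05, in percent (x axis), for 3 comparisons (panels) and 28 lists fixed before the data were examined (y axis), with higher members to the right in red and lower ones to the left in blue. All 35 cell cycle genes fell with passage, and all 35 were higher in Wharton's jelly than in cord tissue.

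Non-coding RNA genes stood among those with the highest log2 fold changes at late passage, including MIR1206 (2.80, SE 0.08), the 5S rRNA pseudogene RNA5SP202 (2.71, SE 0.08) and the C/D box snoRNA gene SNORD114-30 (2.55, SE 0.11). In limma with Benjamini-Hochberg adjustment 14187 of 22347 genes (63.5%) passed, 6772 higher and 7415 lower, and 551 of them changed at least 2-fold. With quantile normalization the split was 4538 higher and 10546 lower. Exogenous poly-A control RNAs, which are added before labelling, differed between the same arrays. Their mean log2 signal was 7.69 ± 0.54 (SD, n = 7) on early and 11.30 ± 0.52 (SD, n = 9) on late arrays, a difference of 3.61 (exact permutation test, two-sided, p = 8.74e-05, the smallest this design allows), with no overlap. The hybridization controls differed less, by 0.92 for bioB, 0.80 for bioC, 0.33 for bioD and 0.22 for cre, with overlap between early and late arrays. Since no early array reached the poly-A level of any late one, array processing and passage cannot be told apart, and whether the same amount of control RNA was added to all samples is not known. With the control level as a covariate, an alternative chosen after seeing the data, 132 genes passed and the cell cycle, DNA replication and interferon lists had no member that passed. The mean change of the cell cycle list was then −0.40 (SE 0.80) against −1.76 (SE 0.18) without it, and that of the interferon list −0.23 (SE 0.69) against 1.32 (SE 0.17), so both the size fell and the error grew. The sign of OAS2 (−0.03), IFI44L (−0.15), COL6A3 (0.31), MYOCD (0.05) and CD44 (0.43) turned in that fit, none past the threshold. Medians of lists turned there too, among them the contractile (−0.21 to 0.10), remodelling enzyme (−0.07 to 0.29), haematopoietic (0.10 to −0.13) and interferon lists (1.44 to −0.18). The cell cycle (−1.72 to −0.38) and collagen medians (0.23 to 0.34) kept their sign.

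**Figure D2:**
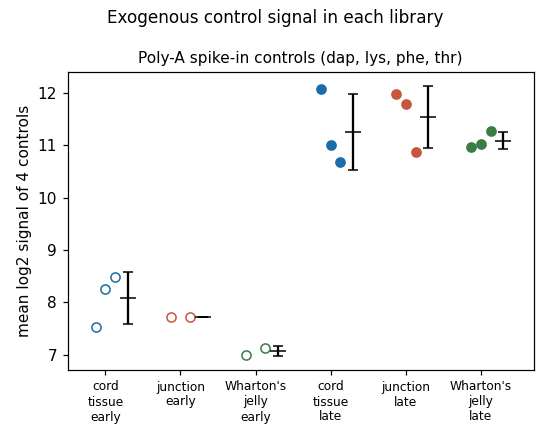
Mean log2 signal of 4 poly-A spike-in controls (y axis) in each library, by group (x axis), with early libraries as open and late libraries as filled points and the mean ± SD of each group as a black bar. Early libraries lay between 6.99 and 8.48 and late ones between 10.7 and 12.1.

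Within single sources, 9489 genes passed between late and early cord tissue, 9856 in the cord-placenta junction and 9001 in Wharton's jelly. The 35 cell cycle genes fell in each source. Interferon response genes rose in 30 of 32 cases in Wharton's jelly, 29 in the junction and 3 in cord tissue, and adjusted over the list alone in 31, 31 and 0 cases. The count of 3 in cord tissue was 1 without early cord tissue replicate 1 or any 1 of the late cord tissue replicates, 6 without late junction replicate 3, and 7 without early Wharton's jelly replicate 1 or 2. In cord tissue ADAMTS5 rose by 3.37 (SE 0.67) and HAS2 fell by 3.27 (SE 0.37). In the junction the protease inhibitor SLPI rose by 3.83 (SE 0.29) and MMP1 fell by 4.08 (SE 0.42). In Wharton's jelly OAS2 rose by 4.32 (SE 0.69) and the cyclin CCND2 fell by 3.08 (SE 0.36). The lower group lay below the background level for 9, 10 and 6 of the 10 genes named in cord tissue, the junction and Wharton's jelly, so such folds may be understated. With quantile normalization the higher share of calls went from 41.6% to 28.5% in cord tissue, from 46.2% to 27.1% in the junction and from 46.7% to 28.3% in Wharton's jelly. With the poly-A control covariate 467, 53 and 62 genes passed. Without cord-placenta junction early replicate 2, 6327 genes passed in the junction, and without Wharton's jelly early replicate 1, 4838 passed in Wharton's jelly. Across genes, the log2 passage changes of cord tissue correlated with those of the junction at Pearson's r = 0.722 and of Wharton's jelly at 0.771, and those of the latter 2 sources at 0.854, with no shared samples. Genes are not independent replicates, so no p-value is given. Cord tissue and junction calls shared 2191 higher and 3319 lower genes, against 803.2 and 1316.3 for independent lists. All 3 changes set late against early arrays, so a processing difference between these arrays would be common to them. The correlations and shared calls cannot tell it from passage.

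The passage change itself differed between sources for 2019 genes in the cord-placenta junction and 576 in Wharton's jelly, each against cord tissue (interaction term in limma, Benjamini-Hochberg adjusted). Against the change in cord tissue, that of RSAD2 was higher by 3.53 (SE 0.59) in the junction and 3.87 (SE 0.59) in Wharton's jelly, and that of the plasminogen activator PLAT by 2.91 (SE 0.30) and 3.25 (SE 0.30). The change of the matrix protein SBSPON was lower by 3.79 in the junction (log2 difference −3.79, SE 0.59) and that of the mechanosensitive channel PIEZO2 was lower in Wharton's jelly (−2.81, SE 0.29). A group lay below the background level for 6 and 5 of the 10 genes named in each, so such differences may be understated. Of the interferon response genes, 16 of 32 in the junction and 20 in Wharton's jelly had a higher passage change than in cord tissue, or 23 and 30 adjusted over the list alone. The junction count of 16 was 10 without early cord tissue replicate 2, 5, 8 and 5 without late cord tissue replicate 1, 2 or 3, 3 and 4 without early junction replicate 1 or 2, 3 without late junction replicate 1 or 2, and 25 without late junction replicate 3. The Wharton's jelly count of 20 was 7 without early Wharton's jelly replicate 1. No cell cycle gene passed this test in either source, but without early cord tissue replicate 3 there were 1 in the junction and 3 in Wharton's jelly, and without late junction replicate 3 there were 5 in Wharton's jelly. The mean of the cell cycle list in late cord tissue, 4.92, lay below the background level of 6.13, so its differences may be understated. For the junction, 775 calls were higher and 1244 lower, against 486 and 1651 with array medians subtracted. The junction count fell to 1199 and 834 without early junction replicate 1 or 2, to 1035 and 1272 without late junction replicate 1 or 2, and to 1084, 1270 and 1108 without late cord tissue replicate 1, 2 or 3. The Wharton's jelly count was 903 without early cord tissue replicate 1, 220 without early Wharton's jelly replicate 1, 328, 377 and 350 without late cord tissue replicate 1, 2 or 3, and 330 and 368 without late Wharton's jelly replicate 2 or 3.

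**Figure D3:**
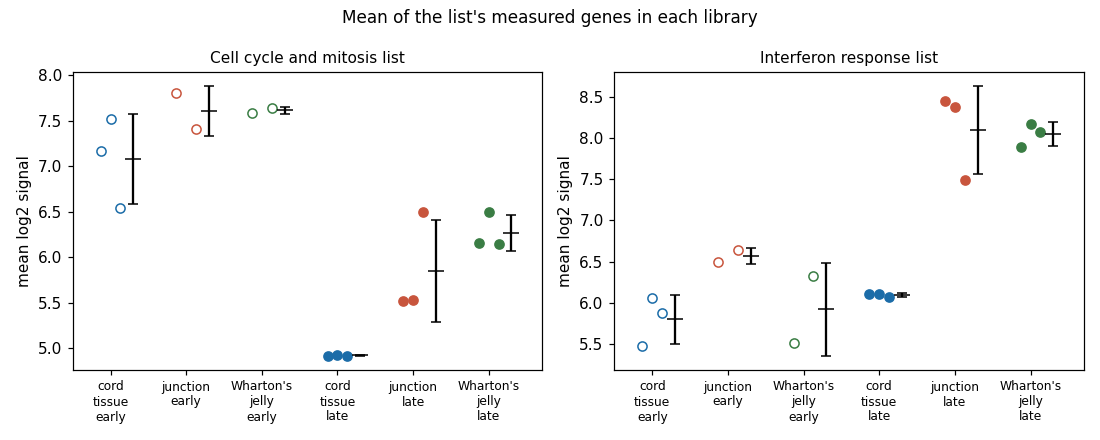
Mean log2 signal over the measured genes of the cell cycle list (left) and the interferon response list (right) in each library (y axes), by group (x axes), with early libraries as open and late libraries as filled points and mean ± SD as black bars. Late cord tissue had the lowest cell cycle mean, 4.92, and an interferon mean of 6.09 against 8.10 in late junction and 8.05 in late Wharton's jelly cells.

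The stated aim of the study was to set cells of the cord-placenta junction and of Wharton's jelly against those of cord tissue. Averaged over both passages, junction cells (n = 5) had higher interferon response genes than cord tissue cells (n = 6). OAS2 was higher by 3.30 (SE 0.46, 9.86-fold), RSAD2 by 2.92 (SE 0.30) and the antiviral gene IFIT1 by 2.30 (SE 0.27), and 30 of 32 members passed, or 32 adjusted over the list alone. Cell cycle genes were higher in 30 of 35 cases (35 adjusted over the list alone), with MKI67 at 1.25 (SE 0.29), and DNA replication genes in 19 of 32 (24 adjusted over the list alone), with TK1 at 0.86 (SE 0.19). By camera these lists gave adjusted p = 1.77e-30, 2.37e-17 and 6.55e-13, and adjusted p = 0.429, 0.465 and 0.446 with an estimated correlation. Without the 2 libraries that stood apart within their groups (cord tissue early 3 and cord-placenta junction late 3, left out after seeing the data), 32, 27 and 17 members were higher. Without early junction replicate 1, 3 cell cycle and 7 DNA replication genes were higher, and without late cord tissue replicate 1 or 3 the cell cycle counts were 17 and 16.

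Some matrix and contractile genes were lower in junction cells and some matrix genes higher. Of 29 contractile and smooth muscle genes 16 were lower and none higher (17 lower adjusted over the list alone), with calponin CNN1 at −1.16 (SE 0.25) and smooth muscle actin ACTA2 at −1.07 (SE 0.12). Of 39 matrix glycoproteins and proteoglycans 18 were lower and 4 higher (24 and 6 adjusted over the list alone), with fibromodulin FMOD at −1.57 (SE 0.16) and biglycan BGN at −0.93 (SE 0.07), but HAS2 at 1.94 (SE 0.28). Of 24 collagens 14 were lower and 4 higher, with COL12A1 at −1.69 (SE 0.09). TGF-beta and BMP response genes were lower in 13 of 31 cases and higher in 3, with the ligand BMP6 at −1.48 (SE 0.21). The unfolded protein and stress list had 16 of 28 lower and 4 higher, HOX and positional genes 17 of 54 lower and 5 higher, and p53 targets and senescence genes 11 of 26 lower and 2 higher. By camera these 7 lists gave, in this order, adjusted p = 2.19e-06, 6.06e-06, 0.000103, 0.000518, 0.00207, 0.00372 and 0.0222. The values were adjusted p = 0.246, 0.225, 0.436, 0.429, 0.522, 0.44 and 0.522 with an estimated correlation. HOXC6 was lower by 1.37 on the log2 scale (log2 difference −1.37, SE 0.07) and HOXC8 likewise (−1.13, SE 0.06). MSC surface markers were higher in 6 of 19 cases and lower in 3, with the aminopeptidase ANPEP at 0.88 (SE 0.08), and cholesterol genes were higher in 4 of 25. These gave adjusted p = 0.013 and 0.0255 by camera, and adjusted p = 0.436 and 0.755 with an estimated correlation. Adjusted over the list alone, lower and higher members numbered 15 and 4 for collagens, 14 and 3 for TGF-beta, 16 and 4 for unfolded protein, 21 and 7 for HOX, 11 and 3 for p53, 4 and 9 for MSC surface markers, and 0 and 5 for cholesterol genes. Without early junction replicate 1, 9 collagens were lower and 1 cholesterol gene was higher, and without late cord tissue replicate 1, 7 p53 and senescence genes were lower. The cholesterol count was 2 without early cord tissue replicate 3, early junction replicate 2, late junction replicate 1 or 2, or any 1 of the late cord tissue replicates. Higher matrix glycoproteins numbered 2 without early junction replicate 2.

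Among the other genes named by the rule, the germline gene MAEL was higher in junction cells by 2.55 (SE 0.11), and the sulfatases SULF2 (−2.00, SE 0.23) and SULF1 (−1.96, SE 0.09) were lower. PARM1 (−2.99, SE 0.44) and the peptidase TRHDE (−2.71, SE 0.56) were also lower. Of the haematopoietic markers only KIT (1.31, SE 0.33) and CD68 (0.57, SE 0.11) passed, and of 27 endothelial markers only FLT1 (−1.21, SE 0.12). Trophoblast markers were higher in 5 of 32 cases, with the pregnancy-specific glycoprotein PSG5 at 0.87 (SE 0.14), and lower in 1. The medians of these 3 lists turned sign with a scaling, and the haematopoietic and trophoblast lists had a median of −0.02 but a mean of 0.12 and 0.07. Of the lists not named so far, higher and lower members numbered 3 and 7 of 31 for remodelling enzymes, 5 and 4 of 36 for secretory factors, 2 and 1 of 28 for NF-kB, 7 and 2 of 27 for immunomodulatory genes, 2 and 7 of 35 for Wnt signalling, 3 and 5 of 34 for hypoxia, 1 and 5 of 17 for decidual markers, and 3 and 1 of 28 for epithelial markers. They numbered 0 and 2 of 18 for osteogenic, 3 and 2 of 22 for chondrogenic, 1 and 3 of 20 for adipogenic, 1 and 0 of 22 for pluripotency and 0 and 2 of 25 for neural genes. None of the lists of this paragraph was called by camera (adjusted p from 0.0708 to 0.966). In limma with Benjamini-Hochberg adjustment 3231 genes passed, 1619 higher and 1612 lower.

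Wharton's jelly cells (n = 5) differed from cord tissue cells (n = 6) along many of the same lists. All 35 cell cycle genes were higher (35 adjusted over the list alone), with MKI67 at 1.69 (SE 0.29) and the centromere protein CENPF at 1.32 (SE 0.27), and 23 of 32 DNA replication genes (31 adjusted over the list alone). Interferon response genes were higher in 26 of 32 cases (29 adjusted over the list alone), with OAS2 at 2.50 (SE 0.46). By camera these lists gave adjusted p = 1.26e-23, 1.92e-17 and 5.6e-21, and adjusted p = 0.436, 0.436 and 0.436 with an estimated correlation. The interferon difference was mostly one of late passage. That list's mean was 5.92 in Wharton's jelly and 5.80 in cord tissue at early passage. At late passage it was 8.05 and 6.09. HAS2 was higher by 2.07 (SE 0.28, 4.20-fold) and the desmosomal protein DSP by 1.74 (SE 0.19). Matrix glycoproteins were lower in 15 of 39 cases and higher in 4, with the fibulin EFEMP1 at −1.67 (SE 0.21) and the laminin LAMA2 at −1.30 (SE 0.12). Contractile genes were lower in 10 of 29 and higher in 0, with ACTA2 at −1.08 (SE 0.12), collagens lower in 9 of 24 and higher in 1, and unfolded protein and stress genes lower in 13 of 28 and higher in 1. Hypoxia and glycolysis genes were higher in 9 of 34 cases and lower in 3, with the carbonic anhydrase CA12 at 0.76 (SE 0.10). By camera these 5 lists gave adjusted p = 0.000273, 0.00198, 0.00215, 0.00472 and 0.000301, and adjusted p = 0.246, 0.436, 0.446, 0.569 and 0.505 with an estimated correlation. The lists of p53 and senescence (8 of 26 lower, 2 higher) and TGF-beta and BMP (11 of 31 lower, 4 higher) gave adjusted p = 0.0016 and 0.0338, and adjusted p = 0.436 and 0.482 with an estimated correlation. Adjusted over the list alone, lower and higher members numbered 17 and 4 for matrix glycoproteins, 11 and 0 for contractile genes, 11 and 2 for collagens, 14 and 3 for unfolded protein, 14 and 2 for p53, 13 and 6 for TGF-beta and 4 and 12 for hypoxia genes. Without early Wharton's jelly replicate 2, 5 unfolded protein, 7 TGF-beta and 5 contractile genes were lower and 2 matrix glycoproteins higher. Lower contractile genes numbered 4 and 6 without late Wharton's jelly replicate 2 or 3, and 6 and 5 without late cord tissue replicate 2 or 3. Without early cord tissue replicate 2, 14 hypoxia genes were higher. The other 18 lists were not called by camera (adjusted p from 0.0708 to 0.968), with at most 7 members higher and 7 lower in any of them. In limma with Benjamini-Hochberg adjustment 3264 genes passed, 1889 higher and 1375 lower, against 1407 with the poly-A control covariate. With that covariate 10 of the 35 cell cycle genes (median 0.73 against 0.97 without it) and 26 of the 32 interferon genes (median 1.11 against 0.92) passed.

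The comparisons of the junction and of Wharton's jelly share the cord tissue arrays. Their log2 fold changes correlated at r = 0.797 across genes, against 0.446 in simulated unchanged groups, and the covariance was 0.0340 against 0.00224. The simulation gave all groups the same spread, although that of early cord tissue was the largest (median SD 0.104), so both simulated values may be too low. With separate cord tissue arrays for each comparison the correlation was 0.628 to 0.732 over 18 ways of dividing them. Both comparisons called 1013 genes higher and 859 lower, against 136.9 and 99.2 for independent lists. The shared cord tissue arrays make these lists dependent, so that reference may be too low.

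Set directly against junction cells (n = 5), Wharton's jelly cells (n = 5) differed in some HOX genes. HOXD10 was higher by 1.72 (SE 0.10), HOXC6 by 1.16 (SE 0.08) and HOXC8 by 0.99 (SE 0.07), and 8 of 54 positional genes were higher and 2 lower, or 14 and 4 adjusted over the list alone. DSP was higher by 2.35 (SE 0.20) and the neuronal gene STMN2 by 1.81 (SE 0.19), whereas MAEL was lower (−3.31, SE 0.12), as was IL6 (−1.19, SE 0.26). All 10 genes named by the rule had a lower group below the background level, so these folds may be understated. The HOX list gave adjusted p = 8.36e-05 by camera and adjusted p = 0.429 with an estimated correlation. The hypoxia list, with 2 of 34 members higher (11 adjusted over the list alone), gave adjusted p = 3.16e-06 and adjusted p = 0.436 with an estimated correlation. The interferon list was lower by camera (adjusted p = 6.7e-07) and the cell cycle and DNA replication lists higher (adjusted p = 0.00159 and 0.018), with adjusted p = 0.639, 0.789 and 0.814 with an estimated correlation. The cholesterol, NF-kB and trophoblast lists were lower (adjusted p = 0.00683, 0.0374 and 0.0374) and the TGF-beta list higher (adjusted p = 0.0221), with adjusted p = 0.735, 0.741, 0.565 and 0.446 with an estimated correlation. In the trophoblast list 1 member passed, and it was higher. The other 19 lists were not called (adjusted p from 0.0523 to 0.975), with at most 4 members higher and 3 lower. No interferon or cell cycle gene passed on its own, and leaving out the 2 libraries that stood apart gave 11 interferon genes lower and 13 cell cycle genes higher. Lower interferon genes numbered 8 without late junction replicate 3 alone, 2 without early Wharton's jelly replicate 2 and 1 without early junction replicate 2. Higher HOX genes numbered 16 without early Wharton's jelly replicate 2. The 2 hypoxia genes became 6 and 5 without early cord tissue replicate 2 or 3, and 4 without early Wharton's jelly replicate 2. They became 1 without early junction replicate 1, late junction replicate 1 or 2, early Wharton's jelly replicate 1 or late Wharton's jelly replicate 3, and 0 without early junction replicate 2 or late Wharton's jelly replicate 2. In limma with Benjamini-Hochberg adjustment 465 genes passed, 266 higher and 199 lower, and 1059 without those 2 libraries. It was 300 without early junction replicate 1, and 306, 284 and 302 without late Wharton's jelly replicate 1, 2 or 3.

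At late passage alone (n = 3 per group), 4514 genes differed between junction and cord tissue cells and 3463 between Wharton's jelly and cord tissue cells. In junction cells RSAD2 was higher by 4.68 (SE 0.40) and SLPI by 3.31 (SE 0.26), and FMOD was lower (−3.15, SE 0.21). In Wharton's jelly cells OAS2 was higher by 4.17 (SE 0.62) and PLAT by 3.27 (SE 0.20), and PIEZO2 was lower (−2.77, SE 0.19). The lower group of RSAD2, SLPI and FMOD lay below the background level, as for 7 and 6 of the 10 genes named in each comparison, so such folds may be understated. Interferon response genes were higher in 31 and 30 of 32 cases (32 and 30 adjusted over the list alone), and cell cycle genes in 25 and 34 of 35 (32 and 35 adjusted over the list alone). The junction count of 25 was 10 without late junction replicate 3, where the list mean went from 0.93 to 0.61, and 11 without any 1 of the late cord tissue replicates. Of the 14 haematopoietic markers the median differed by 0.04 and 0.02, and KIT (2.37 and 1.62) and CD68 (0.52 and 0.51) made up most of a higher mean, 0.235 (SE 0.054) and 0.158 (SE 0.054). Matrix glycoproteins were lower in 24 and 16 of 39 cases and higher in 4 and 5, or 2 for the junction without late cord tissue replicate 1 and 3 for Wharton's jelly without late Wharton's jelly replicate 1. Without Wharton's jelly late replicate 2, 2180 genes passed for that source.

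At early passage few genes passed, which need not mean few differences, since the spread of early cord tissue was the largest (median SD 0.104). Between junction and cord tissue cells 18 genes differed by limma, 10 higher and 8 lower, against 12 and 6 with quantile normalization and 23 and 8 with array medians subtracted. MAEL was higher by 2.18 (SE 0.16) and LINC02864 by 1.58 (SE 0.10), and SULF1 (−1.05, SE 0.14) and B3GALT2 (−1.04, SE 0.13) were lower. Between Wharton's jelly and cord tissue cells 3 genes passed: the BMP antagonist GREM1 (−0.60, SE 0.07), B3GALT2 (−0.93, SE 0.13) and PCOLCE2 (0.43, SE 0.06). With quantile normalization 1 call was higher and 1 lower, and with array medians subtracted the 1 call was higher. The lower group lay below the background level for 3 of the 4 and 2 of the 3 genes named, so such folds may be understated. No member of the interferon, cell cycle or DNA replication lists passed over all genes. Adjusted over the list alone, 19 interferon and 18 DNA replication genes were higher in the junction, and 0 and 18 in Wharton's jelly. Without early cord tissue replicate 2, 5 interferon, 2 cell cycle and 4 DNA replication genes passed in the junction and 1 DNA replication gene in Wharton's jelly, and without early Wharton's jelly replicate 1 or 2, 3 interferon genes passed in the junction. At an unadjusted p under 0.05, 3765 and 3705 genes passed. Without early cord tissue replicate 2 the counts were 768 and 438, without replicate 3 they were 9 and 0, and without replicate 1 the Wharton's jelly count was 62. Without early junction replicate 2 the junction count was 30, and without early Wharton's jelly replicate 1 or 2 it was 68 and 68, and the Wharton's jelly count 32 and 20. Leaving out any 1 of late junction replicates 1 and 2 and the late replicates of the other sources gave 6 to 11 genes for the junction and 0 for Wharton's jelly. Fold changes at early and late passage correlated across genes at r = 0.41 for the junction (Spearman's rho 0.12) and 0.449 for Wharton's jelly (rho 0.325), with no shared samples, so for the junction the ranks of genes were less related than r alone shows.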

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

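The tests on the poly-A control difference, the cell cycle list, the background probes and the haematopoietic markers were chosen only after the result was seen, and the poly-A control covariate, also used for the interferon list, was added after the control difference was seen.

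The first pattern is the 63.5% of genes that differed between passages, on arrays whose poly-A controls, a signal outside the gene measurements, also differed by 3.61 on the log2 scale with no overlap. Chance can be excluded for these arrays only. Of 100 splits of the passage labels within sources, out of 2000 possible, only the real one called as many genes (14187, highest other 9717). The splits took each array as a separate unit, so they cannot exclude chance differences between single cultures. Separate processing of early and late arrays may account for an unknown part of the calls, since the control difference that it needs was there, but another amount of added control RNA would give that difference too and was not tested, and a biological effect of passage, untested apart from it, stays open. Passage and processing cannot be told apart for genes that moved alike in all sources. The fall of the cell cycle list differed between Wharton's jelly and cord tissue by 0.81 (SE 0.44), within 2 standard errors, but by 1.12 (SE 0.44) with the poly-A control covariate, so this test leaves open whether a run difference common to late arrays covers that list. The list's mean in late cord tissue, 4.92, lay below the background level of 6.13, so the difference in falls may be understated.

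The second pattern is the rise of small RNA genes, which made up 63.8% of the 293 genes at least 2-fold higher at late passage but 9.3% of all genes. Higher background on late arrays is argued against for part of them: of 325 small RNA genes above the background level at early passage, 39 (12%) rose by more than 1.46, the largest rise of any background probe set. For the others it stays open, since background sets with 3 to 10 GC bases rose by 0.195 to 0.587. Separate processing remains open, because within groups the small RNA mean and the poly-A control mean correlated at r = 0.245 (rho = 0.171, permutation p = 0.523, 16 samples; r = 0.402 without the 2 farthest), which decides nothing. Passage itself is also open and was not separately tested.

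The third pattern is the higher interferon list in late junction and Wharton's jelly cells than in late cord tissue. Its passage change exceeded that of cord tissue by 1.24 (SE 0.41) in the junction and 1.83 (SE 0.41) in Wharton's jelly, a difference between groups by the interaction term. As far as the poly-A controls track labelling, unequal labelling of the late arrays is argued against, since with the poly-A control covariate the smaller of the late differences was 1.89 (SE 0.24). Haematopoietic cells stay open: the median of their 14 markers differed by at most 0.039, but only 2 of them lay above the background level, and while their mean was higher by 0.235 (SE 0.054) and 0.158 (SE 0.054), KIT (2.37 and 1.62) and CD68 (0.52 and 0.51) made up most of it, against PTPRC at −0.03 and −0.01, CD14 at −0.07 and −0.12 and TYROBP at 0.06 and −0.01. A biological difference between the sources may remain as a hypothesis, but differences between single cultures stay open, because nothing says that the samples of a group were separate cultures.

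The passage change also differed between groups for 2019 genes in the junction and 576 in Wharton's jelly, each against cord tissue. For the mean comparisons between sources, a share of splits under 0.05 called as many genes as the real one, for these arrays only. In each of them another split called more genes than the real one, so chance is not excluded. Of 100 splits, 3 gave as many genes as junction against cord tissue (3231, highest other 3398). For Wharton's jelly against cord tissue it was 2 of 100 (3264, highest other 4171), and for Wharton's jelly against the junction 2 of 60 (465, highest other 499). The 10 splits of 3 against 3 are too few for a share under 0.05. The real split, 1 of the 10, gave 9489 genes for passage in cord tissue (highest other 0), 4514 for late junction (highest other 1) and 3463 for late Wharton's jelly against cord tissue (highest other 0).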

How the results depend on the processing

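The poly-A control covariate, the omission of small RNA genes and the omission of both outlying libraries were chosen after seeing the data. Comparisons are given in the order passage mean; junction, then Wharton's jelly, against cord tissue (means); Wharton's jelly against the junction; the 2 early, the 2 late and the 3 passage comparisons by source; and the 2 interactions. The poly-A control covariate moved the passage mean from 14187 to 132 genes, Wharton's jelly against cord tissue to 1407, Wharton's jelly against the junction to 216, the early comparisons to 7 and 0, passage by source to 467, 53 and 62, and the interactions to 1070 and 255. Early and late controls did not overlap, so by construction that fit has larger errors for passage. It also turned the sign of 30 gene results of the passage mean, none past the threshold: OAS2 −0.031, MCAM 0.022, CD44 0.431, KIT −0.135, CD68 −0.051, CD14 −0.236, CD38 −0.028, GDF3 −0.108, RFC3 0.098, IGFBP3 −0.053, PTGES −0.163, IFI44L −0.153, IFIT2 −0.581, IFIH1 −0.127, TNFSF10 −0.722, COL6A3 0.306, MYOCD 0.045, ACTG2 0.347, ANKRD1 0.236, CNN1 0.288, ACTA2 0.044, SOX9 0.04, ADIPOQ −0.095, TFAP2A −0.048, GPX3 0.301, SOX18 0.009, PSAT1 0.08, SFRP1 0.297, LGALS9 −0.337 and TLR3 −0.37. The mean of a gene's probes turned CD44 to 0.26. Of 588 results of 327 named genes under 28 settings, 14805 of 15874 values kept direction and side of the threshold, 1038 lost the call and these 31 reversed.

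Testing every probe gave 41010, 5001 and 865 calls for the passage mean, the junction mean and Wharton's jelly against the junction, 66 and 0 early, 7947 and 5254 late, and 24289, 25716 and 23793 for passage by source, since more probes were tested. A 2-fold minimum, stricter by construction, left 551, 157, 131, 29, 4, 0, 431, 376, 642, 662, 642, 235 and 143 genes with adjusted p, and 551, 158, 132, 33, 38, 21, 436, 390, 644, 669, 647, 282 and 235 with unadjusted p. Array weights gave 777 for Wharton's jelly against the junction, 6 and 0 early, and 6906 and 6287 late. With only the compared groups the early comparisons gave 0 and 0, late Wharton's jelly 6001 and the junction interaction 1162. Without both outlying libraries Wharton's jelly against the junction gave 1059, its early comparison with cord tissue 0 and its interaction 1091. Early junction against cord tissue gave 31 with array medians subtracted, 31 without dim genes, 30 with a trended and robust prior, 11 with the mean of a gene's probes, 6 without the late junction samples and 31 without small RNA genes. Early Wharton's jelly gave 1 with array medians subtracted and 1 without the late junction samples. For these moves the cause was not tested. Replicate numbers did not pair the samples in general: 36 same-number pairs had a median residual correlation of −0.03 and 70 other pairs 0.02. Of 15 pairs of groups, only early junction and early Wharton's jelly had same-number correlations that all exceeded 0.1 (0.336). Each of these groups had 2 samples, whose deviations mirror each other, so this is 1 value. With the replicate block the early comparisons gave 10 and 0 genes. Camera made 0 of its 37 calls with an estimated correlation, and 32 of them with quantile normalization. The 5 lost there were cholesterol with passage (adjusted p = 0.147), MSC surface markers (0.0552) and cholesterol (0.147) in the junction against cord tissue, and TGF-beta (0.059) and trophoblast (0.0728) in Wharton's jelly against the junction. The filter on dim genes kept 36 calls, losing cholesterol in the junction against cord tissue (adjusted p = 0.0831), and omitting both outlying libraries kept 36, losing MSC surface markers there (0.0523). The correlation between the late source comparisons was 0.735 over every probe against 0.796, and 0.502 in simulated unchanged groups, because both share the late cord tissue arrays.

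Leaving out 1 replicate at a time gave 13005 to 14790 genes for the passage mean, 2195 to 3992 and 2202 to 4212 for the means against cord tissue, 284 to 677 for Wharton's jelly against the junction, 6 to 768 and 0 to 438 early, 3265 to 5391 and 2180 to 4226 late, 7491 to 9778, 6327 to 10828 and 4838 to 10010 for passage by source, and 834 to 2934 and 220 to 903 for the interactions. The correlation of the late source comparisons ranged from 0.76 to 0.803, to be set against the same 0.502. The alternatives not named for a comparison kept its count within 1.5 times. The samples of the passage mean already were those of the groups compared, and comparisons with late junction cells could not be made without them. Signal over background limits the rest: at most 37.0% of genes lay above the background level of an array, a level that follows the highest background sets.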

Other observations

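The gene families here were chosen after their values were seen. The imprinted SNORD113 and SNORD114 snoRNA families rose at late passage in 38 of 40 measured members, with 1 lower and a median of 1.47 on the log2 scale. In each source 37 of the 40 rose and 1 fell. Of the SNORD115 and SNORD116 families 35 of 50 rose on average over sources (median 0.23), but in the junction 9 rose and 11 fell (median 0.05). Of the other C/D box snoRNA genes 42 of 84 rose and 15 fell (median 0.17), with 21 and 16 in the junction. Differences between these families were not tested. H/ACA box snoRNA genes rose in 51 of 64 cases (median 0.51), spliceosomal RNA genes and pseudogenes in 196 of 213 (median 0.46), and 5S rRNA genes and pseudogenes in 376 of 483 (median 0.26). Replication-dependent histone genes fell in 24 of 38 cases and rose in 6 (median −0.35). These medians over sources kept their sign with quantile normalization and with array medians subtracted, and the difference in poly-A controls applies to all of them. Rises were not limited to small RNA classes. Olfactory receptor genes rose in 194 of 393 cases and fell in 26 (median 0.095). Long intergenic non-coding RNA genes rose in 233 of 537 and fell in 49 (median 0.081, or −0.01 with quantile normalization). Zinc finger genes rose in 81 of 510 and fell in 239. Background probe sets with 3 to 10 GC bases also rose at late passage, by 0.195 to 0.587 on the log2 scale. That range reaches or exceeds the rises above other than that of SNORD113 and SNORD114. The background set with 25 GC bases rose by 1.46, about the median rise of SNORD113 and SNORD114. Probe GC content of the families was not compared with that of these sets.

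Pregnancy-specific glycoproteins, which the placental trophoblast secretes, were higher in junction than in cord tissue cells for 7 of 10 measured genes on average over passages. This count was 9 of 10 at late passage (median 0.63) and 0 of 10 at early passage (median 0.16). In Wharton's jelly 1 of 10 was higher than in cord tissue on average, 4 at late passage (median 0.45) and 0 at early passage (median −0.11). Signal shared between the similar probes of this family was not tested.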
